A study of Homo sapiens with 2 samples.

How the data were processed

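RNA from MKN45 cells, a human line of poorly differentiated gastric adenocarcinoma, was measured on 2 arrays. Per the labels, 1 culture had been transfected with a negative control siRNA (NC siRNA) and 1 with an siRNA against CUL4B, each for 48 h. Total RNA was extracted with Trizol and reverse transcribed from oligo dT primers, per the labels' protocols. The same protocols name both an RNA amplification kit and Cy3 labelling of double-stranded cDNA, so the labelling route remained unsettled. Groups were taken from the sample titles.

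Each sample's file held single-colour Cy3 intensity values, deposited as the scanner software wrote them. Spots had been quantified with Agilent Feature Extraction 11.0.1.1 on array design 026652, and the design was annotated to GRCh37, per the file headers. Both arrays lay on the same slide and were read in the same scan, per the file headers. Each array had 44495 spots, of which 43118 were not controls and carried 34127 different probes. Of these probes, 999 were spotted 10 times. The processed intensity used here had been background-subtracted and spatially detrended by the authors' scanner software, with no scaling between arrays, per the file headers. The authors also deposited a table of 34183 log2 values per array, with the method not given in the sources used here. Both of its columns had a median of 6.74 and the same quartiles, which is how quantile-normalized values look. Across probes, each column correlated with log2 of its own array's processed intensity (r = 0.999 for both) more than with the other array's (r = 0.989 for both). That table was used only as an alternative.

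Processed intensities were taken to log2, and each array's 75th percentile over all spots that were not controls was subtracted. The percentile lay at an intensity of 687 on the NC siRNA array and 957 on the CUL4B siRNA array. Spots marked as outliers by the scanner software were left out (392 on the NC siRNA array and 286 on the CUL4B siRNA array). No spot was saturated. Remaining spots of a probe were averaged, and a probe was used if more than 50% of its spots were well above background on each array. Of the spots that were not controls, 77.1% were well above background on the NC siRNA array and 76.7% on the CUL4B siRNA array.

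Probes were named by matching their accession, without version, to NCBI RefSeq gene records of assembly GRCh38.p14, which were used for names only because the builds differ. Of the 34127 probes, 25771 matched a gene and 8356 did not. The named probes covered 19740 genes. A gene's value was the mean over its probes well above background on both arrays, which left 15478 genes, 3562 of them with at least 2 such probes. Differences are given as CUL4B siRNA minus NC siRNA on the log2 scale. Another 395 genes were well above background on the NC siRNA array only, 293 on the CUL4B siRNA array only and 3569 on neither. For genes seen on a single array, a lower bound of the fold was computed against the higher of the dim probe's own value and the lowest value well above background on that array.

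There was 1 array per group and no replicate, so no test between the groups was possible, and no p-value is given. Culture, transfection, RNA preparation and labelling each occurred once per group and cannot be told apart from the siRNA. The only error measured was that between spots of the same probe within an array, taken from the probes spotted 10 times in 5 bins of brightness. The SD of a difference from this source was 0.36 in the dimmest bin, 0.13 in the next and between 0.07 and 0.09 in the other 3. It is called the spot SD below, and it leaves out all variation between cultures, labellings and hybridisations. For a gene, it was taken at the gene's mean signal and divided by the square root of its number of measured probes. It can thus be too small where the probes of a gene differ in brightness. It was not reduced for probes spotted 10 times. Most probes were spotted once, so for them this error was borrowed from other probes.

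The following choices were made before the data were examined. Genes at least 2-fold higher or lower were counted. The genes named are, per direction, up to 12 with the largest difference among those brighter than the median gene, with a proper gene symbol and with every measured probe at least 2-fold apart in the same direction. Up to 3 genes per direction seen on a single array with the largest bounds, and CUL4B and ERBB2, are also named. From each of 36 gene lists, up to 4 measured members with the largest absolute difference are named, as are members past 2-fold. Some genes that these rules pick, and 1 of the lists, are not reported here. The lists held 1097 symbols, of which 3 matched no current gene symbol, and included markers of fibroblasts, immune cells, endothelium, and red and liver cells. A list was said to stand apart when the median difference of its measured members, at least 5, lay below percentile 2.5 or above percentile 97.5 of 10000 random lists of the same size matched on mean signal in 20 bins. That percentile describes these 2 arrays only. By construction, 5% of random lists stand apart. Random genes were drawn singly, whereas genes of a list can vary together between any 2 cultures, so that share does not apply to the lists themselves.

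Alternatives covered scaling to the median, no scaling, quantile normalization, cyclic loess, the authors' log2 table, normexp background correction with an offset of 50 followed by quantile normalization, and no background correction. Others used the brightest probe of a gene, no filter on dim probes, brighter genes only, spots marked as outliers kept, saturated spots left out, and thresholds of 1.5-fold and 3-fold. Both alternatives on the background used the median spot intensity, since the mean spot intensity that had been planned for them was not analysed here. That replacement, and a count of genes with at least 2 probes past 2-fold, were chosen after seeing the data.

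The steps were tested on simulated differences for the 15478 genes with the spread seen between these arrays. Of 100 genes given a log2 difference of 1.5, 90% were recovered past 2-fold, and of 100 given 2, 100% were. Of the 15278 genes given no difference, 0.48% lay past 2-fold. Of 200 random lists, 4% stood apart, and a list of 30 genes raised by 0.3 reached percentile 99.4. Analyses used R 4.3.3 with limma 3.58.1, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.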

Results

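Gene expression was profiled in MKN45 gastric cancer cells 48 h after transfection with a negative control siRNA (NC siRNA, 1 array) or an siRNA against CUL4B (1 array). The comparison asks which transcripts differ when CUL4B, the scaffold subunit of a family of cullin-RING ubiquitin ligases, is silenced. The series title points in particular to HER2, the receptor tyrosine kinase encoded by ERBB2. Levels on both arrays could be compared for 15478 genes, and across these genes the arrays correlated with r = 0.991, genes not being independent replicates. There were no replicates, so every difference below is between 2 arrays and carries only the error between spots.

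CUL4B was 3.39-fold lower in the CUL4B siRNA array (log2 difference -1.76, spot SD 0.10). Its 2 probes were 4.10-fold and 2.81-fold lower. Among the 15478 genes, CUL4B had the 31st lowest difference. CUL4A, the paralogous scaffold, had a log2 difference of 0.39 (spot SD 0.05), with its 2 probes at 0.22 and 0.56. ERBB2 was 1.06-fold lower (log2 difference -0.09, spot SD 0.08, 1 probe), a difference of about the size of the spot error. With the arrays scaled to their medians the ERBB2 difference was 0.00, and without scaling, which moves the median of all genes up by 0.48, it was 0.39. CUL4B remained lower in each of these (-1.67 and -1.28).

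More genes were lower than higher in the CUL4B siRNA array. At least 2-fold lower were 202 genes (1.31%), against 26 at least 2-fold higher (0.168%), and 98.5% lay within 2-fold. In the simulation with the spread seen between these arrays, 0.48% of genes given no difference lay past 2-fold, directions not split. That spread already holds any effect of the siRNA or of the cultures, so the simulation cannot show whether the 26 higher genes exceed error. All 26 higher genes and 188 of the 202 lower ones rested on a single probe. Among genes brighter than the median gene, 46 were lower and 1 was higher. Only 3 genes had at least 2 measured probes that were all 2-fold lower, namely CUL4B, STPG3 and ADARB2, and none had this in the higher direction. ADARB2, an RNA editing deaminase chosen after its values were seen, had dim probes, with a spot SD of 0.36 each. Lower genes made up 88.6% of those past 2-fold. Their share was smaller with median scaling (81.0%), after cyclic loess (76.8%) or quantile normalization (75.3%), and with no filter on dim probes (74.9%). It was 73.8% in the authors' log2 table (which moves the median of all genes up by 0.10) and 19.8% without scaling (54 lower, 219 higher). The share was larger after normexp (96.2%), with no background correction (98.9%), over brighter genes (97.9%) and with the brightest probe (89.3%).

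The gene with the largest named difference was RNA18SN5, a copy of the 18S ribosomal RNA gene, at 9.76-fold lower (log2 difference -3.29, spot SD 0.07). This RNA has many near-identical gene copies, so the assignment to 1 of them is uncertain. SIX6, a homeobox transcription factor of eye and pituitary, was 7.28-fold lower (-2.86, spot SD 0.08). Its probe was spotted 10 times, and all its spots were lower on the CUL4B siRNA array than on the NC siRNA array. C3AR1, the receptor for complement C3a, was 5.11-fold lower, and IPW, a non-coding RNA of the imprinted Prader-Willi region, 3.99-fold lower. The retinoic acid binding protein gene CRABP1 was 3.38-fold lower, but its difference was -0.68 with no filter on dim probes. The cytoglobin gene CYGB was 3.06-fold lower and CIDEB, which encodes a lipid droplet protein, 3.26-fold lower. PSD, an exchange factor for ARF GTPases, was 3.68-fold lower, and the sialic acid binding lectin gene SIGLEC15 3.65-fold lower. STPG3 was 3.28-fold lower, with its 2 probes at -1.72 and -1.71. RNF222 was 3.51-fold lower by its measured probe, but its other probe, well above background on the CUL4B siRNA array only, was in the opposite direction. The sole gene named in the higher direction was FKBP10, a peptidyl-prolyl isomerase of the endoplasmic reticulum, at 2.27-fold higher (1.18, spot SD 0.07). Apart from STPG3, each of these genes rested on a single measured probe.

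**Figure D1:**
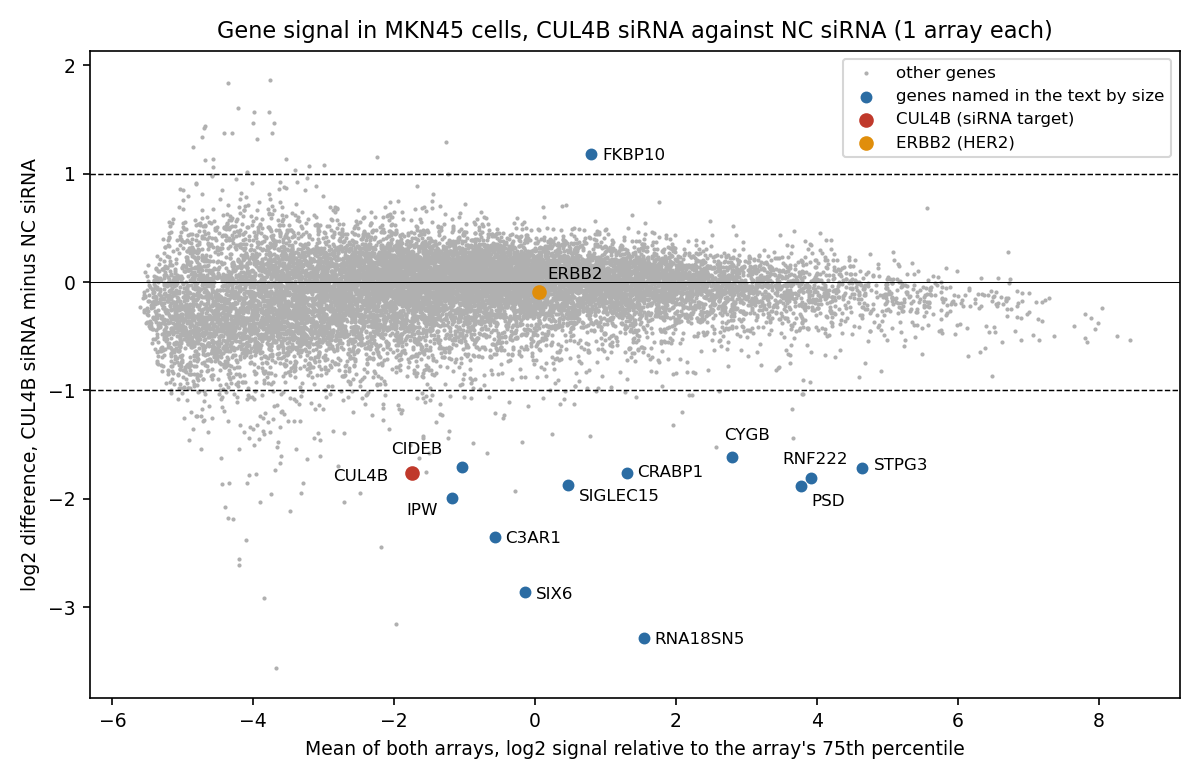
Each point is a gene, placed by its mean log2 signal over both arrays relative to each array's 75th percentile (horizontal axis) and by its log2 difference, CUL4B siRNA minus NC siRNA (vertical axis), with dashed lines at 2-fold. CUL4B lies at -1.76, ERBB2 at -0.09, and the genes named by size lie between -3.29 and -1.61 except FKBP10 at 1.18.

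Some genes were well above background on a single array. ECRG4, which encodes a secreted peptide precursor, was at least 10.4-fold lower in the CUL4B siRNA array, C11orf16 at least 6.45-fold lower and the sarcolipin gene SLN at least 5.08-fold lower. In the other direction, the myelin protein gene NCMAP was at least 6.58-fold higher, the olfactory receptor gene OR10A3 at least 5.40-fold higher and PLAC9 at least 5.08-fold higher. Each of these 6 genes rested on 1 probe and was picked by the size of its bound. The bounds allow for no error between spots, which was largest among dim probes (spot SD 0.36 in the dimmest bin). The bound exceeded 2-fold for 86 of the 395 genes seen on the NC siRNA array only and for 36 of the 293 seen on the CUL4B siRNA array only.

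Of the 36 gene lists, 3 stood below matched random lists and 8 above them. Their position relative to random lists had the same sign under all 12 alternatives. The median differences of the 8 also stayed above 0 throughout, while those of the 3 were above 0 without scaling (histones 0.03, gastric lineage 0.09, immune markers 0.13) and below 0 otherwise. No list had a member at least 2-fold higher. Of 143 members with the largest differences in their lists, 39 had the opposite sign without scaling and 8 under at least 1 other alternative, and 53 lay over 1.5 times nearer 0 after normexp and 25 with no background correction.

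Histone genes formed the list farthest below random lists, with a median of -0.45 over 41 genes (percentile 0.00) and 37 genes below 0. The linker histone gene H1-5 had a log2 difference of -0.94 (spot SD 0.13), and the core histone genes H2BC7, H2BC3 and H2BC9 had differences of -0.83, -0.83 and -0.78 (spot SD 0.09, 0.07 and 0.09). Replication-dependent histone genes, whose transcripts mostly end without a poly(A) tail, had a median of -0.52 over 33 genes, all 33 of them below 0. The 7 replacement histone genes, whose transcripts are polyadenylated, had a median of -0.05. H2AX, whose transcripts occur in both forms, was left out of this division. The division was made after part of the histone values had been seen, and without scaling the medians were -0.04 and 0.43.

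Cell division genes lay on the other side. Mitotic genes had a median of 0.13 over 34 genes (percentile 100), with 30 above 0. The mitotic kinesin gene KIF20A had a log2 difference of 0.44, the kinetochore gene CENPF 0.37 and the checkpoint kinase gene BUB1B 0.31, while cyclin F (CCNF) stood at -0.38 (spot SD 0.36). DNA replication and S phase genes had a median of 0.06 over 38 genes (percentile 97.8), and percentiles of 96.6 after normexp, 95.3 with no background correction and 97.2 with no filter on dim probes no longer stood apart. Their median lay 0.08 above that of matched random lists, no farther than housekeeping reference genes did (0.09, percentile 95.9). In the S phase list the helicase gene MCM4 had a difference of 0.44, whereas GINS1, another component of the replicative helicase, had -0.84 and the nucleotide synthesis genes RRM2 and TK1 had -0.49 and -0.35.

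**Figure D2:**
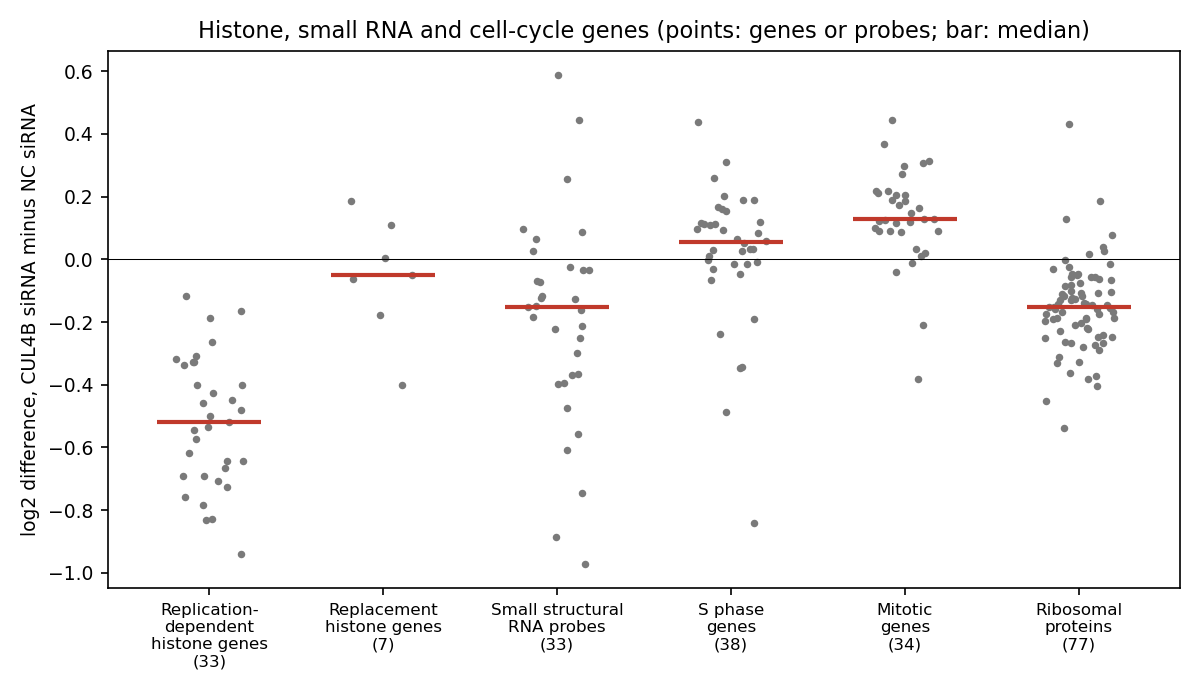
Points are genes, or probes for the small structural RNAs, and bars are medians of the log2 difference, CUL4B siRNA minus NC siRNA, in 6 groups whose sizes stand in brackets. The median is -0.52 for replication-dependent histone genes and -0.05 for replacement histone genes (-0.04 and 0.43 without scaling), -0.15 for small structural RNAs, and 0.06 and 0.13 for S phase and mitotic genes.

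Adhesion genes also stood above random lists. Integrin, laminin and focal adhesion genes had a median of 0.14 over 33 genes (percentile 99.99), with 23 above 0. The collagen-binding integrin gene ITGA2 had a difference of 0.46, but other members went the opposite way. The kinase gene SRC stood at -0.69 and the hemidesmosome integrin gene ITGB4 at -0.42.

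Hypoxia and glycolysis genes had a median of 0.11 over 34 genes (percentile 99.99). Carbonic anhydrase CA9 had a difference of 0.53 (spot SD 0.36), the glycolytic regulator PFKFB4 0.40 and lactate dehydrogenase LDHA 0.39, against -0.88 for the phosphofructokinase gene PFKL. Heat shock protein genes had a median of 0.14 over 21 genes (percentile 99.98), with the chaperone genes HSP90AB1 at 0.44 and HSPA2 at 0.45 and the stress-inducible HSPA6 and HSPA1B at -0.72 and -0.44. HSPA1B has a near-identical copy, so its value is uncertain. Proteasome subunit genes had a median of 0.09 over 35 genes (percentile 99.9, and 97.1 after normexp), with PSMC5 at 0.40 and PSMD6 at 0.35, and PSMB3 and PSME1 at -0.42 and -0.40 (spot SD 0.36 for PSME1). NF-kappaB and inflammatory genes had a median of 0.08 over 28 genes (percentile 99.2). The cytokine genes IL1A and IL6 had differences of 0.51 (spot SD 0.36, and 0.04 with no background correction) and 0.31, the apoptosis inhibitor BIRC3 0.35 and the growth factor CSF1 -0.41. Percentiles of 95.6 after normexp and 95.1 over brighter genes no longer set this list apart.

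Genes of cullin-RING ligases and neddylation, a list that includes CUL4B itself, had a median of 0.08 over 46 genes (percentile 99.7). Beside CUL4B and CUL4A, the substrate receptor gene DCAF1 had a difference of 0.42 and the signalosome subunit gene COPS8 0.41 (spot SD 0.25 for both, and 0.03 and 0.11 with no background correction). The list no longer stood apart with no background correction (percentile 97.47) or with the brightest probe of each gene (86.6).

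Gastric lineage genes were below random lists, with a median of -0.39 over 17 measured genes (percentile 0.190) and 15 below 0. The mucin gene MUC6 was 2.60-fold lower (-1.38, and -0.90 without scaling), with its 2 probes at -1.92 (spot SD 0.07) and -0.84 (spot SD 0.36). The secretory cell transcription factor gene BHLHA15 had a difference of -0.93 and gastrin (GAST) -0.83, while annexin A10 (ANXA10) stood at 0.91, all with a spot SD of 0.36. Intestinal lineage genes had a median of -0.20 over 15 genes (percentile 21.4), with the surface antigen gene GPA33 at -0.63, the trefoil factor gene TFF3 at -0.59, the homeobox gene CDX1 at -0.53 and ALPI at -0.48.

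Immune cell markers were below random lists too, with a median of -0.35 over 14 measured genes (percentile 0.410) and 12 below 0. The adaptor genes TYROBP and FCER1G had differences of -0.69 and -0.56, the integrin gene ITGAM -0.51 and the Fc receptor gene FCGR3A -0.46 (spot SD 0.36). On the NC siRNA array, log2 levels relative to the 75th percentile were 5.64 for ITGAM, close to the keratin gene KRT7 at 5.57, and -5.02 for FCGR3A. MKN45 is a cancer cell line, so these values cannot be read as immune cell content, and the specificity of the probes was not examined. Markers of other cell types lay within the random range. Endothelial markers had a median of -0.18 over 7 genes (percentile 32.2). One of them, the adhesion molecule gene PECAM1, was 4.21-fold lower by its measured probe (-2.07, spot SD 0.36, and -0.69 after normexp), with 2 further probes below background. FLT1 and CDH5 stood at -0.62 (spot SD 0.36, and -0.01 after normexp) and -0.33. Fibroblast markers had a median of 0.04 over 8 genes (percentile 75.5), with FBN1 at 0.45, FAP at 0.40 (spot SD 0.36), DPT at -0.31 and DCN at 0.29. Red and liver cell markers had a median of -0.23 over 7 genes (percentile 9.98), with HBA2 at 0.75 from 3 probes between -0.23 and 1.56, ALAS2 at -0.56 and FGB at 0.48 (spot SD 0.36).

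**Figure D3:**
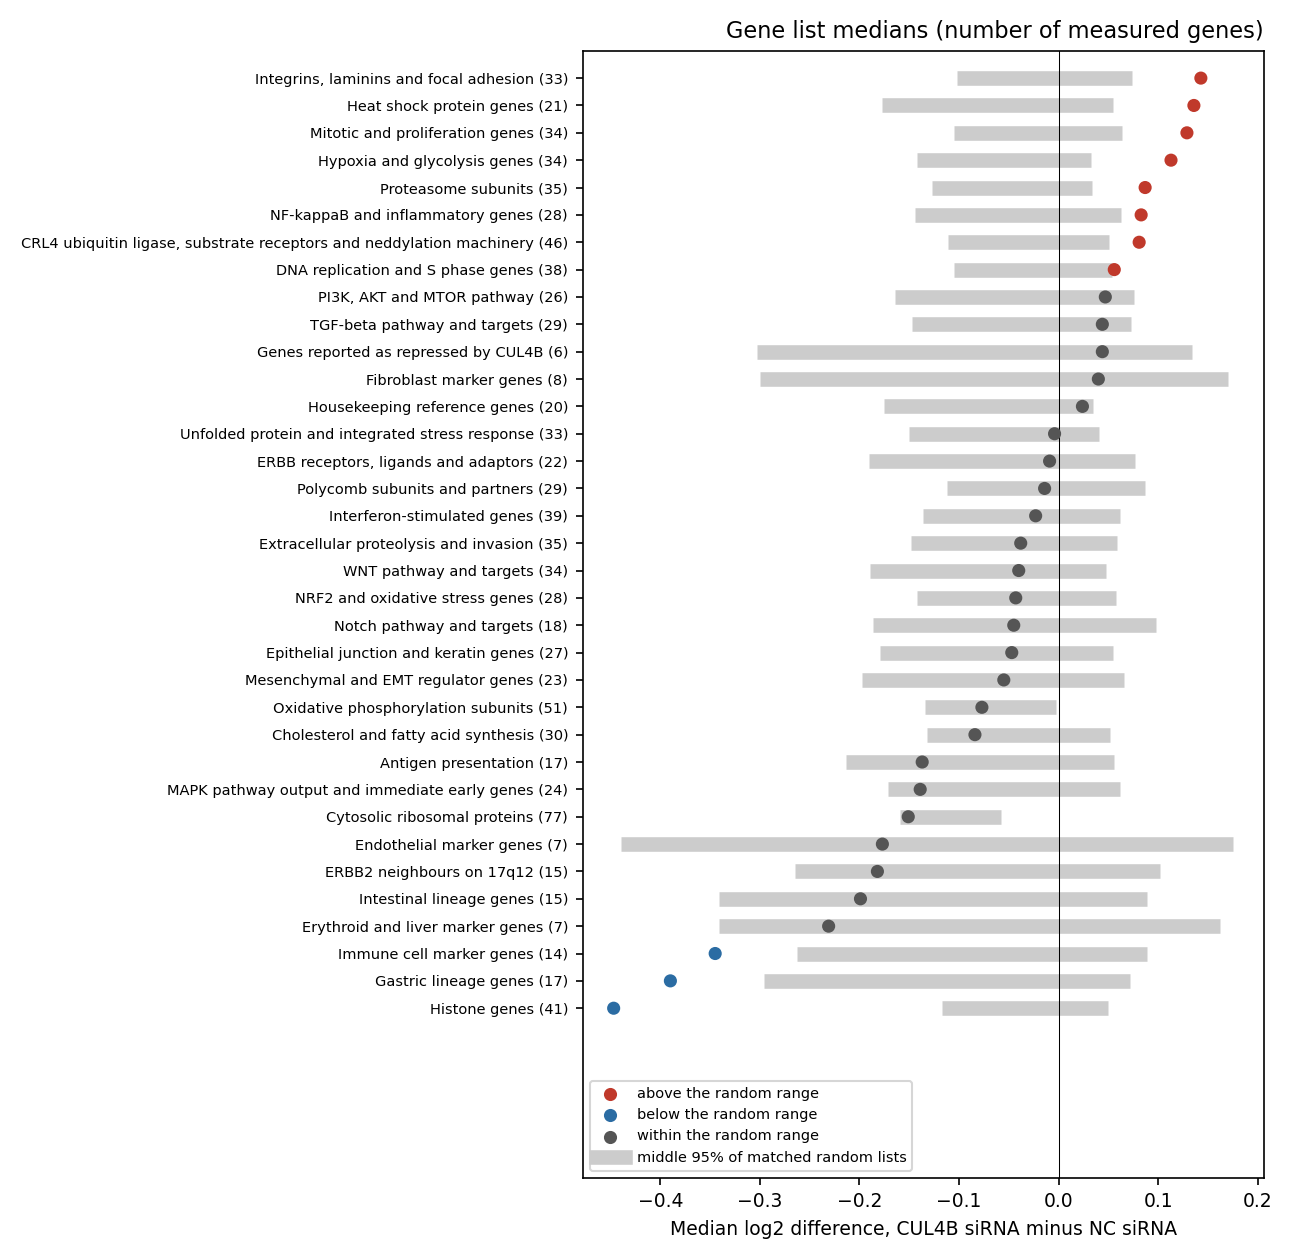
Each point is the median log2 difference of a gene list, CUL4B siRNA minus NC siRNA, with its number of measured genes in brackets, and grey bars span the middle 95% of matched random lists. Histone (-0.45), gastric lineage (-0.39) and immune marker genes (-0.35) lie below their bars, all 3 being above 0 without scaling, and 8 lists from S phase genes (0.06) to integrins and laminins (0.14) lie above.

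ERBB receptors, ligands and adaptors lay within the random range, with a median of -0.01 over 22 genes (percentile 70.2). The ligand gene EREG had a difference of 0.47 and the adaptor GRB2 0.40, against -0.44 for the adaptor GRB7 and -0.40 for EGF (spot SD 0.36). For EREG the spot SD was 0.09, but differences of all genes in its bin of brightness had an SD of 0.24. The neighbours of ERBB2 at 17q12, which include GRB7, had a median of -0.18 over 15 genes (percentile 11.5, and 2.45 after normexp). Among them PGAP3, MED24 and ORMDL3 had differences of -0.60, -0.60 and -0.59, and PPP1R1B had -0.50 (spot SD 0.36). MAPK pathway output genes had a median of -0.14 over 24 genes (percentile 5.90). The immediate early genes EGR3, JUNB and EGR1 had differences of -0.73 (spot SD 0.36, and -0.25 after normexp), -0.55 and -0.52, and the transcription factor gene ETV4 had 0.54. This list stood apart at percentile 2.36 after quantile normalization, 1.84 with no filter on dim probes and 1.78 over brighter genes. PI3K, AKT and MTOR pathway genes had a median of 0.05 over 26 genes (percentile 92.2, and 97.8 with no background correction), with MTOR at 0.38, PIK3CB at 0.35, PDPK1 at 0.34 and AKT1 at -0.37.

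Of the lists linked to invasion, the mesenchymal, epithelial and proteolysis ones did not stand apart, unlike the adhesion list above. Genes reported as repressed by CUL4B and Polycomb subunits did not stand apart either. Mesenchymal and EMT regulator genes had a median of -0.05 over 23 genes (percentile 48.5). The matrix protein gene SPARC had a difference of -0.85, COL6A2 had -0.43, CTNNB1 -0.43 from probes at -0.78 and -0.07, and COL5A1 -0.25 from probes at -0.51 and 0.01. Epithelial junction and keratin genes had a median of -0.05 over 27 genes (percentile 55.1), with the splicing regulator ESRP1 at -0.58 and the transcription factor GRHL2 at 0.54 (spot SD 0.36 for both, and -0.07 for GRHL2 with no background correction), KRT7 at -0.40 and CLDN7 at -0.27. Extracellular proteolysis genes had a median of -0.04 over 35 genes (percentile 49.4), with HGF at -0.65 (spot SD 0.36), MMP19 at -0.63, TIMP4 at -0.41 and MMP17 at -0.39. Genes reported as repressed by CUL4B had a median of 0.04 over 6 genes (percentile 85.8), with the growth factor binding protein gene IGFBP3 at 0.17, the cell cycle inhibitors CDKN1A and CDKN2A at -0.16 (spot SD 0.36) and -0.15, and the WNT inhibitor DKK1 at 0.08. The sign of the last 3 depended on the processing. Polycomb subunits had a median of -0.01 over 29 genes (percentile 44.8), with CBX7 at -0.78 from probes at -1.72 and 0.15, JARID2 at -0.53, PCGF2 at -0.43 and BMI1 at 0.26.

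Signalling lists within the random range were TGF-beta (median 0.04, percentile 91.7), WNT (-0.04, 64.7) and Notch (-0.05, 44.2). Among their members, the matricellular gene CCN1 had a difference of -0.42 and SOX9 0.64 (spot SD 0.36). Notch members went both ways, with 8 above 0 and 10 below, NOTCH4 at 0.89 and the Notch target gene HES1 at -0.73 (spot SD 0.36 for both), the ligand gene JAG1 at 0.52 and LFNG at -0.34. Interferon-stimulated genes had a median of -0.02 over 39 genes (percentile 57.6). Among these IFI35 was 2.78-fold lower (-1.47, spot SD 0.08), IFI6 stood at -0.72 and USP18, which removes ISG15 from proteins, at 0.68. Antigen presentation genes had a median of -0.14 over 17 genes (percentile 17.2), with HLA-C at -0.45. HLA genes are closely related in sequence, so the value of HLA-C is uncertain.

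The lists that follow were likewise within range. Unfolded protein and integrated stress response genes had a median of 0.00 over 33 genes (percentile 83.0), with CHAC1 at -0.94, ATF3 at -0.55 from 4 probes between -1.38 and -0.02, and the cystine transporter gene SLC7A11 at 0.48. NRF2 and oxidative stress genes had a median of -0.04 (percentile 46.2), with GSR at -0.55 from probes at -0.90 and -0.20, and SQSTM1 at 0.51. Cholesterol and fatty acid synthesis genes had a median of -0.08 (percentile 15.4), with FADS1 at -0.45 and HMGCS1 at 0.37. Oxidative phosphorylation genes had a median of -0.08 over 51 genes (percentile 37.3), with ATP5F1B at 0.43 and NDUFB1 at -0.35. Cytosolic ribosomal protein genes had a median of -0.15 over 77 genes (percentile 4.58, and 1.22 with no filter on dim probes), which was above 0 after quantile normalization (0.05), cyclic loess (0.01), normexp (0.04), in the authors' log2 table (0.05) and without scaling (0.33). RPS18 and RPS27A had differences of -0.54 and -0.45 and RPL27A 0.43. Housekeeping reference genes had a median of 0.02 over 20 genes (percentile 95.9), above 0 under every scaling tried, with CTCF at 0.44, EEF1A1 at 0.38 and PPIA at 0.26. They stood above random lists under 5 of the 12 alternatives, at percentiles of 99.3 after quantile normalization, 99.6 after cyclic loess, 98.8 after normexp, 98.5 in the authors' log2 table and 98.2 with the brightest probe.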

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

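Of the tests below, those on the S phase list and on brighter small structural RNAs were chosen only after their results were seen. So were the ribosomal RNA values other than that of RNA18SN5 and the count of 13 genes. Bootstrap intervals below give only the spread among the resampled genes or probes on this pair of arrays. They leave out all variation between cultures, labellings and hybridisations.

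Probes without a gene name, which entered no comparison, also differed between the arrays. Of 5281 such probes well above background on both arrays, 179 (3.39%) were at least 2-fold lower in the CUL4B siRNA array and 23 (0.436%) at least 2-fold higher. Among 19730 named probes the shares were 1.45% and 0.223%.

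More genes were at least 2-fold lower than higher (202 against 26), a split turned round only when the arrays were not scaled. A trend of the difference with brightness as the whole cause is argued against, since 149 genes were lower and 45 higher after cyclic loess. Loss of the whole transcript was tested in 93 genes with a 2-fold lower probe and another measured probe. Their other probes had a median of -0.22 (95% bootstrap interval over genes -0.30 to -0.16), above the -0.5 set in advance. For those 93 genes as a set, though not for each gene, this argues against a whole-transcript loss reaching -0.5. A smaller loss stays open, since the median of all genes was nearer 0 (-0.05). Picking genes by their lowest probe also favours probes that are low by error. For the 202 genes loss of the whole transcript stays open, since only 13 of the 93 were among them and 188 of the 202 had a single measured probe. Defects of single spots could account for part of the pattern and also stay open. All 3 named probes that were both 2-fold lower and spotted 10 times (SIX6, BAX and APH1A, the last chosen after its values were seen) had every CUL4B siRNA spot below every NC siRNA spot. That decides little, since picking probes by the mean of 10 spots nearly fixed this outcome. The 3 probes also leave the share anywhere from 0.292 to 1 (exact binomial interval). Most probes were spotted once, and the test does not cover them. A lower share of RNA without a poly(A) tail stays open too: 33 probes of small structural RNAs had a median of -0.15 (95% bootstrap interval over probes -0.25 to -0.07), short of the -0.5 set in advance, but many were near the floor, the 13 brighter than the median gene had -0.39 (interval -0.56 to -0.12), and ribosomal RNA probes lay between -3.29 and 1.41. An effect of the siRNA, on CUL4B or elsewhere, cannot be separated from differences between the 2 cultures or labellings.

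Replication-dependent histone genes were lower in the CUL4B siRNA array, with a median of -0.52 (-0.04 without scaling). The 95% bootstrap interval over genes was -0.64 to -0.43. Histone genes are not independent replicates, and cross-hybridisation among their probes was not examined. Transcripts of the S phase list were not lower as a group: it lay at percentile 97.8 of random lists, with 25 of its 38 genes above 0 and 13 below. Fewer cells in S phase nevertheless stays open. The test was chosen after its result was seen, and levels of these transcripts do not count cells in S phase. A lower share of transcripts without a poly(A) tail in the labelled material may contribute, since the replacement histone genes lay 0.47 above the replication-dependent ones (interval 0.28 to 0.67, and 0.42 to 0.54 across alternatives). It cannot be told apart from a change in histone transcripts themselves, because the small structural RNAs do not decide: their median was -0.15 over all 33 probes, but the interval of the 13 brighter ones (-0.56 to -0.12) reaches the median of the histones. No biological explanation beyond the S phase one was tested.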

How the results depend on the processing

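The alternatives were set beforehand except the median spot intensity, used for both background alternatives, and the count needing 2 probes, both chosen after seeing the data. CUL4B was lower under all 11 alternatives that gave it a value, at -1.28 without scaling, -1.31 after normexp, -1.47 with no background correction and -2.03 with its brightest probe. Over brighter genes only it had none, being dimmer than the median gene. ERBB2 moved to 0.00 with median scaling and 0.39 without scaling, and lay between -0.11 and -0.05 otherwise. Genes at least 2-fold higher and lower numbered 219 and 54 without scaling, 2 and 51 after normexp, 1 and 90 with no background correction, 212 and 632 with no filter on dim probes and 1 and 46 over brighter genes. The higher count alone moved by over 1.5 times, from 26 to 47 after quantile normalization, 45 after cyclic loess and 48 in the authors' log2 table. At 1.5-fold the counts were 143 and 1057, at 3-fold 3 and 44, and with at least 2 probes agreeing 0 and 3. RNF222 reversed to 1.02 with no filter on dim probes, where a probe below background on the NC siRNA array entered its mean. Calls past 2-fold ended for CRABP1 (-0.68) with no filter on dim probes, PECAM1 (-0.69) after normexp, and MUC6 (-0.90) and narrowly IFI35 without scaling. Other causes were not tested. Lists standing apart numbered between 10 and 13, against 11. Those of integrins, mitosis, hypoxia, heat shock, histones, gastric lineage and immune markers stood apart under all 12 alternatives, proteasome under 11, cullin-RING ligases and NF-kappaB under 10 and S phase under 9. Leaving out saturated spots moved nothing, since none was saturated. Signal over background limits precision among dim probes: the SD of gene differences was 0.42 in the dimmest bin and 0.24 in the brightest. No paired analysis was possible because each group had 1 array.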

Other observations

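The ribosomal RNA probes below and ADARB2 were chosen only after their values were seen, and no explanation of them was tested.

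Ribosomal RNA probes differed widely between the arrays and not all in the same direction. The 2 brightest probes of RNA28SN5, a copy of the 28S ribosomal RNA gene, had log2 differences of -1.59 and -1.42, while its other 2 probes had 1.41 and 0.80. The brightest had a processed intensity of 310019 on the NC siRNA array and 143763 on the CUL4B siRNA array. RNA5-8SN5, a copy of the 5.8S gene, had -1.95 by 1 probe. These RNAs have many near-identical gene copies, and probes of the same RNA disagreed in direction.

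Some genes had probes that disagreed within the same gene. RNF222 had a probe at -1.81 and another, below background on the NC siRNA array, that was well above background on the CUL4B siRNA array. By contrast, the 2 measured probes of ADARB2 were close to each other, at -1.09 and -1.14, but with a spot SD of 0.36 each this closeness says little. Probe sequences and the siRNA sequence were not used here, so neither cross-hybridisation nor transcripts matched by the siRNA were examined.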
